A study of Mus musculus with 7 samples.

How the data were processed

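The series holds 7 RNA sequencing libraries of cells sorted from mouse brain at stage E14.5. Of these, 3 are control and 4 are Tgfbr2-deficient libraries, grouped by the genotype given in the labels. Per the labels, total RNA was extracted from sorted cells with a micro-scale column kit, complementary DNA was made with the SMART-Seq v4 ultra-low-input kit, which primes on poly(A) tails and amplifies by PCR, and libraries were built by Nextera XT tagmentation. Neither kit marks the strand, so reads from overlapping and antisense genes cannot be separated. Per the submitters' processing notes, the genome build was mm10 and the tools were TopHat2, Cufflinks 2.2.1 and Cuffdiff. The gene annotation, the library normalization and the test options are not given in the sources used here.

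The authors' deposited table is gene-level Cuffdiff output, per the file headers, with the control group first and the Tgfbr2-deficient group second. Its FPKM values, per the file headers, are 1 value per group and gene that the authors' Cuffdiff made from the libraries of the group, so the replicates are already combined. The deposited log2 fold is that of the Tgfbr2-deficient over the control FPKM with no pseudocount, and it differed from the log2 ratio of the FPKM values by at most 3.6e-05. The deposited test statistic, a score for the log fold, was used only to check that its sign followed the fold. The p-value and q-value of each gene are those of the authors' Cuffdiff test, as deposited, and the smallest p-value, 5e-05, was shared by 2357 tested genes, so genes could not be ranked below it. The table held 0 columns of values per library. Counts were not analysed here, so the depth per library is unknown, and it could not be said how much of the precision of a low FPKM is set by depth. Amplification from 2000 to 5000 cells adds noise to transcripts of low abundance, which Cuffdiff's test sees only as spread between libraries.

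The design, the gene lists, the threshold and the filter were fixed before the data were examined. The main count took genes with the authors' test status OK, at 1 FPKM or more in at least 1 group, and called them higher or lower at a deposited q-value under 0.05. Folds quoted for lists are log2 of (FPKM + 1) in the Tgfbr2-deficient over the control group, so 0 FPKM is allowed and genes near 1 FPKM are pulled towards 0. Of 672 list symbols, 640 matched a row of the table, 15 of them through synonyms in a RefSeq gene table of the GRCm38.p6 assembly, and each gene was counted once per list. For each list the calls were compared with those of all other tested genes by a two-sided Fisher's exact test per direction, adjusted by Benjamini and Hochberg over 34 lists and both directions. Each list median was also placed among 10000 random lists of the same size matched on mean expression in 20 bins. Genes in a list are not independent replicates, so these tests describe how calls are distributed over genes and add no replication. Differences between list medians were tested by two-sided permutation of genes between the lists, with 100000 permutations. On simulated data for this comparison, with 13356 genes and lists of 20 genes, 0 of 30 unchanged lists passed either measure. All 5 of 5 lists with a planted log2 fold of 1 and 5 of 5 with a log2 fold of 2 passed both. The calls of a random share of the planted genes were set to the planted direction, so their Fisher's exact result was largely built in. Folds and calls were shuffled between genes of similar expression, which removes correlation between genes, so the unchanged lists do not show the error rate of real lists.

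The genes named were Tgfbr2, then the 10 genes with the largest rise and the 10 with the largest fall in log2(FPKM + 1) among those past the threshold whose row names a single gene, then for each list up to 4 members with the smallest p-value among those past the threshold, or the 2 most abundant where none passed. Ties at the smallest p-value were ordered by the size of the fold, a choice made after seeing the data. Other genes are named where they moved against their list, where a count was small or as examples, and these were chosen after their values were seen. Some genes that this rule names are not reported here. Coordinates are those of the authors' deposited table in mm10, counted from 1. They were compared with the GENCODE M21 annotation of GRCm38, the same assembly, in which 21659 symbols were found and 21454 of them (99.1%) overlapped the annotated gene. Another 96 rows of the table name several symbols and were counted but not named.

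Alternatives fixed beforehand were no FPKM filter, a filter of 5 FPKM, q under 0.01, a log2 fold of at least 1 in addition, q-values recomputed over the filtered genes, rows of several symbols left out, folds centred on the median of tested genes, a pseudocount of 0.1 FPKM and matching in 10 bins. Alternatives chosen after seeing the data were centring on ribosomal protein genes, recomputed q-values for Tgfbr2 and the named genes, the marker lists left out of the count, marker genes left out of the other lists, and a pseudocount of 0.1 FPKM in the comparisons between endothelial lists. A test per library, a replicate block, leaving out each library and other splits of the libraries could not be run on group values. No genes were left out for their function, and the 6 globin entries with the status HIDATA, at 4 distinct positions because overlapping entries share coordinates, given where a locus holds too many fragments, were kept out of all tests. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.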

Results

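The series compared brain cells labelled endothelial from mouse embryos at stage E14.5. They were labelled as controls or as lacking Tgfbr2, the type II receptor of transforming growth factor β (TGF-β). There were 3 control and 4 Tgfbr2-deficient libraries. Cells were sorted on TdTomato, a red fluorescent protein that the Ai14 reporter allele makes in cells where Cre recombinase has acted, and each library came from 2000 to 5000 cells. The Cre driver and the deleted exons are not given in the sources used here. RNA abundance was read from single-end reads of 50 bases. The values analysed were 1 FPKM value per gene and group (fragments per kilobase of transcript, scaled to library size), as given by the authors. No values per library were analysed here, so the spread between libraries could not be computed and their depth was unknown. No confidence intervals or detection floors were therefore set, and the q-values in the authors' deposited table are the error measure for single genes. The labels do not state that the libraries of a group came from separate embryos, so these q-values measure only the spread between these libraries, which may be technical. Of 23358 gene entries, the authors tested 14043, left 9309 untested and gave 6 a status for too many fragments. Differences were counted among the 13356 tested genes at 1 FPKM or more in at least 1 group.

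Tgfbr2 itself did not pass as different between the groups. It stood at 91.1 FPKM in the control group and 65.4 FPKM in the Tgfbr2-deficient group. The authors' deposited table gives this gene a log2 fold of −0.48 with p = 0.0433 and q = 0.0953, which did not pass the threshold of 0.05. On FPKM + 1 its log2 fold was −0.47, and it becomes 0.0700 when centring on ribosomal protein genes adds 0.54 to every log2 fold. In the mm10 build the locus lies on chromosome 9 from 116087695 to 116175363, where GENCODE M21 annotates the protein-coding gene ENSMUSG00000032440.13 on the minus strand from 116084293 to 116175360. A gene-level FPKM can include reads from exons that remain after recombination, so the value does not measure how much functional transcript was left. The macrophage median fell by 1.12 in the same groups, so the level of Tgfbr2 does not separate a loss of its transcript from a change in the mix of cells.

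Across all tested genes, the median of macrophage markers stood above that of pan-endothelial genes in both groups and most macrophage markers fell in the Tgfbr2-deficient group, while most markers of endothelial, mural, connective tissue, blood and neural cells rose. Csf1r, the receptor on which macrophages depend, went from 1247 to 494 FPKM, and C1qa, a complement component that microglia make, from 1070 to 523 FPKM. Kdr, the main signalling receptor for VEGF-A on endothelium, went from 1.94 to 43.0 FPKM, and Cldn5, the claudin of brain endothelial tight junctions, from 5.02 to 74.9 FPKM. By the q-values in the authors' deposited table, 3195 of the 13356 genes were higher in the Tgfbr2-deficient group (23.9%) and 1966 were lower (14.7%), while 8195 did not pass the threshold. The higher genes had a median of 1.47 FPKM in the control group and 5.27 FPKM in the Tgfbr2-deficient group, and the lower genes of 43.6 and 25.1 FPKM. A fold of at least 2 was reached by 2688 of the higher genes and 368 of the lower genes. At a minimum of 5 FPKM the counts were 1643 higher and 1865 lower, so the larger number of higher genes depended on genes of low abundance.

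**Figure D1:**
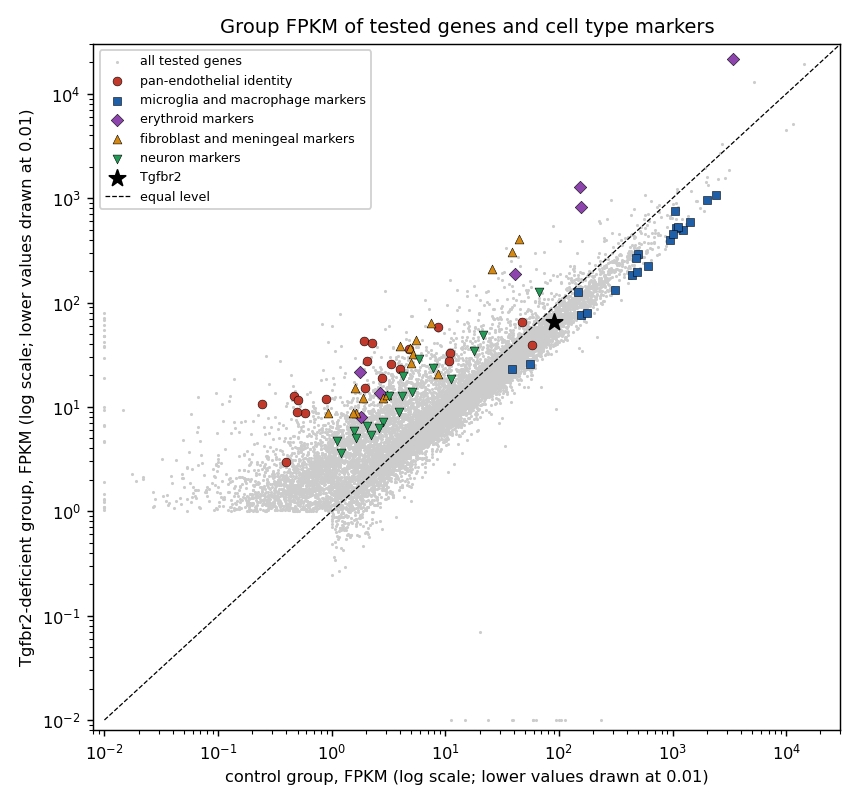
Authors' group FPKM of each tested gene in the control group (horizontal axis) and the Tgfbr2-deficient group (vertical axis), both on log scales, with values below 0.01 drawn at 0.01. Coloured symbols mark members of 5 cell type lists, the star marks Tgfbr2 (91.1 and 65.4 FPKM) and the dashed line marks equal levels. Of the marker lists drawn, only that of microglia and macrophages lies below the line as a group, with 18 of 20 members lower.

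The 10 genes with the largest rises on the log2(FPKM + 1) scale included 4 genes of mast cells and 3 of megakaryocytes and platelets, a grouping made after the genes were seen and not tested. Cma1, a mast cell chymase, rose from 1.18 to 78.3 FPKM, Hdc, which makes histamine, from 0.818 to 62.6 FPKM, Cpa3, the mast cell carboxypeptidase, from 2.93 to 129 FPKM, and Tpsb2, a tryptase, from 1.01 to 59.6 FPKM. Tubb1, the tubulin of platelets, rose from 0.264 to 30.9 FPKM, Itga2b, a platelet integrin, from 0.925 to 42.2 FPKM, and Mmrn1, which platelets and endothelium store, from 0.138 to 18.6 FPKM. Adm, the vasoactive peptide adrenomedullin, rose from 0.353 to 27.3 FPKM and Cav1, the coat protein of caveolae, from 1.22 to 38.0 FPKM. Each of these 9 genes had q = 0.00029, the smallest in the authors' deposited table. The remaining gene, the microRNA locus Mir100, was listed at 0 FPKM in the control group and 79.7 FPKM in the Tgfbr2-deficient group, with q = 0.0143 in the authors' deposited table.

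The 10 genes with the largest falls on the same scale included Fos, an immediate-early transcription factor, which fell from 354 to 106 FPKM. Crybb1, a crystallin that microglia of the embryo also express, fell from 53.8 to 15.6 FPKM. Aoah, which inactivates bacterial lipopolysaccharide in myeloid cells, fell from 37.9 to 11.1 FPKM, and Clec12a, a myeloid lectin, from 19.5 to 6.0 FPKM. Gpr165, an orphan receptor, fell from 10.6 to 2.36 FPKM, the homeobox gene Lbx1 from 11.8 to 2.84 FPKM, the histone gene Hist1h2bg from 14.1 to 3.64 FPKM, the carrier gene Slc25a45 from 56.7 to 18.5 FPKM and 4930404N11Rik from 49.4 to 15.4 FPKM. The largest q among these 9 genes was 0.0086, for 4930404N11Rik, in the authors' deposited table. The microRNA locus Mir19a was listed at 62.3 FPKM in the control group and 0 FPKM in the Tgfbr2-deficient group, with q = 0.0427 in the authors' deposited table. Mir19a lies within Mir17hg and Mir100 overlaps 3110039I08Rik, Gm48742 and Gm49317, so their reads cannot be told from those of the overlapping genes, and no fold is given against a group listed at 0. Hist1h2bg belongs to a family of near-identical histone genes and is uncertain for the same reason.

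Gene lists chosen before the data were examined show how far the genes of each cell type or pathway moved as a set. A list median does not separate a change in a pathway from a change in the mix of cells. Some lists share members, such as the arterial and Notch lists with 6, so counts of lists are not counts of separate results. Of 34 lists with tested members, 24 held more higher genes than the other tested genes and 3 held more lower genes, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 34 lists and both directions. These tests were not matched on expression, on which calls depended. Of the 1336 tested genes in the lowest 10% by mean expression 715 were higher and 26 lower, and of the 1336 in the highest 10% 80 were higher and 549 lower. The median log2(FPKM + 1) fold of 25 lists lay above the central 95% of 10000 random lists matched on expression, and that of 1 list, the microglia and macrophage markers, lay below it. List medians here are on that scale, which understates the change of genes of low abundance. With 0.1 FPKM added in place of 1 FPKM, the medians of 10 lists moved by more than the median absolute deviation of their members. They became 2.60 for tip cell, 2.40 for arterial, 2.01 for SMAD1/SMAD5 response, 2.92 for VEGF axis, 1.73 for endothelial-to-mesenchymal transition, 2.44 for protease, 2.70 for pericyte, 1.52 for neuron, 1.76 for neural progenitor and 1.71 for oligodendrocyte-lineage genes. Within that deviation, the barrier median became 2.09 and the integrin median 1.17. The median over all tested genes was −0.08, and centring on ribosomal protein genes, a choice made after seeing the data, adds 0.54 to every log2 fold. In 23 lists the counts adjusted over the list alone were those over all genes tested, and the others are given beside their list. Members that moved against their list are named below after their values were seen. The mitochondrially encoded genes were not analysed here.

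Of the markers of cell types other than endothelium, those of microglia and macrophages fell, while 6 other lists held more higher genes than the other tested genes did and that of the oligodendrocyte lineage did not pass. Fcrls, a scavenger receptor of microglia, fell from 611 to 225 FPKM, Sfpi1, the myeloid transcription factor PU.1, from 491 to 197 FPKM, the Fc receptor chain Fcer1g from 1414 to 589 FPKM and the fractalkine receptor Cx3cr1 from 312 to 132 FPKM. Of 20 microglia and macrophage markers, 18 fell and 0 rose (adjusted Fisher's exact p = 9.4e-12), and the list median fell by 1.12 on the log2 scale. Lyz2, at 1054 and 753 FPKM, was among those that did not pass. The list's median level was 554 FPKM in the control group and 278 FPKM in the Tgfbr2-deficient group, 256 and 11.4 times the medians of the pan-endothelial genes. Fall and rise here are relative to the other RNA in each group, since FPKM carries no absolute amount.

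Markers of connective tissue and of the vessel wall rose in the Tgfbr2-deficient group. Col1a1, which encodes type I collagen, rose from 44.1 to 404 FPKM, Col3a1 from 38.8 to 305 FPKM and Col6a1 from 3.98 to 38.1 FPKM. All 17 fibroblast and meningeal markers rose (adjusted Fisher's exact p = 6.0e-10), with a median log2 fold of 2.41. Of 16 pericyte and smooth muscle markers, 11 rose and 0 fell (adjusted Fisher's exact p = 6.6e-04), with a median of 1.89. They included Pdgfrb, the PDGF receptor of pericytes, from 2.63 to 16.8 FPKM, Rgs5 from 0.762 to 8.03 FPKM and Myl9, a myosin light chain of smooth muscle, from 4.46 to 45.0 FPKM.

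Erythroid markers rose, and so did 7 of 10 platelet and granulocyte markers. Alas2, the enzyme that starts haem synthesis in erythroid cells, rose from 153 to 1282 FPKM and the embryonic globin Hbb-bh1 from 155 to 819 FPKM. All 7 tested erythroid markers rose (adjusted Fisher's exact p = 2.0e-04), with a median log2 fold of 2.39. Another 6 globin entries at 4 positions, the largest Hbb-y at 24570 FPKM in the control group, were listed at 0 FPKM in the Tgfbr2-deficient group under the status for too many fragments and have no test. Of 10 platelet and granulocyte markers, 7 rose and 1 fell (adjusted Fisher's exact p = 0.0067, lost at 0.232 when genes were called at q under 0.01), with a median of 2.25, and 8 rose when adjusted over the list alone. Gp9, a platelet glycoprotein, rose from 0.843 to 22.8 FPKM and Mpo, the peroxidase of granulocytes, from 2.23 to 29.9 FPKM, while Pf4, a platelet chemokine also made by macrophages, fell from 1877 to 747 FPKM.

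Markers of neurons and neural progenitors rose. Neurod6 and Neurod2, transcription factors of cortical neurons, rose from 5.86 to 28.8 and from 4.24 to 19.9 FPKM, and Slc1a3, the glutamate transporter of radial glia, from 1.92 to 10.3 FPKM. All 19 neuron markers rose (adjusted Fisher's exact p = 5.1e-11), with a median log2 fold of 1.19. Of 16 neural progenitor markers 15 rose (adjusted Fisher's exact p = 5.7e-08), with a median of 1.39, and 0 fell over all genes tested and 1 when adjusted over the list alone. Of 9 oligodendrocyte-lineage markers 5 rose and 1 fell (adjusted Fisher's exact p = 0.0819, 0.0472 when genes were called at q under 0.01 and 0.256 at a minimum of 5 FPKM), or 6 and 1 adjusted over the list alone. Sox10, a transcription factor of this lineage and of neural crest, rose from 1.44 to 7.57 FPKM.

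**Figure D2:**
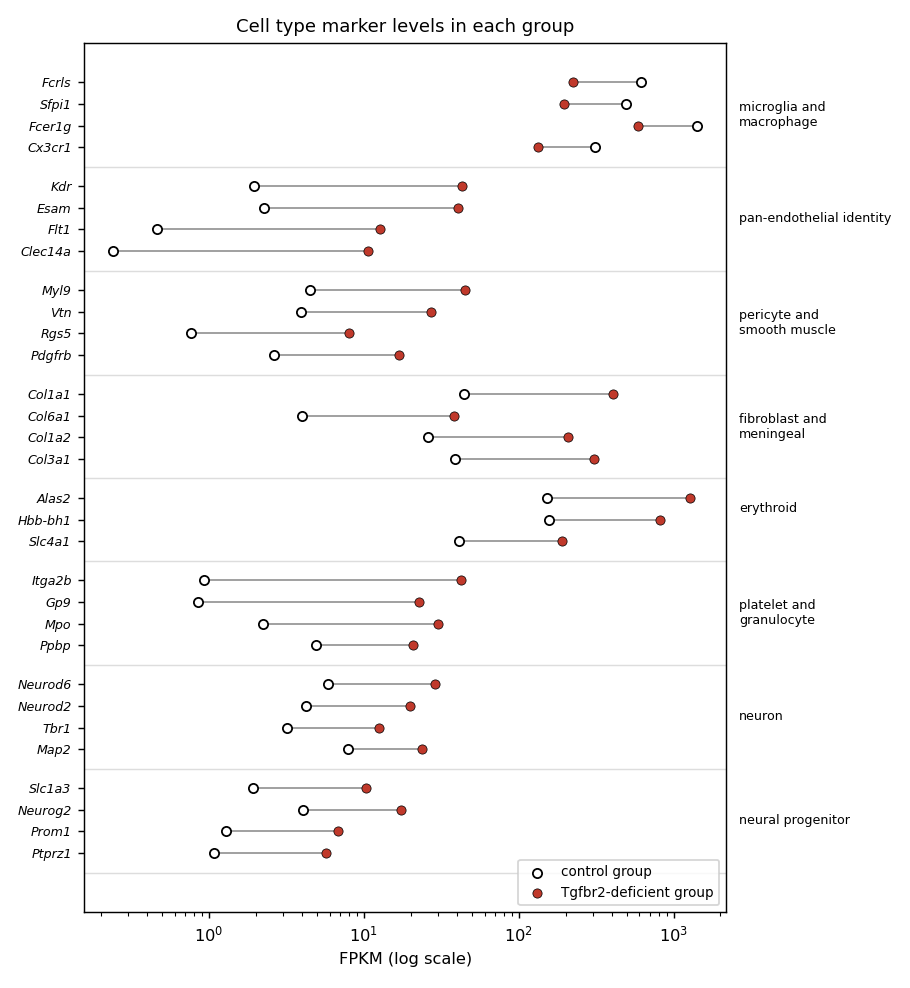
Authors' group FPKM (horizontal axis, log scale) of up to 4 named genes from each of 8 cell type lists, with open circles for the control group, filled circles for the Tgfbr2-deficient group and a line joining the 2 values of a gene. Fcrls, Sfpi1, Fcer1g and Cx3cr1 moved down, as Fcer1g from 1414 to 589 FPKM, and the named genes of the other 7 lists moved up, as Kdr from 1.94 to 43.0 FPKM.

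Genes of endothelial identity rose together. Besides Kdr, Esam, an adhesion molecule of endothelial junctions, rose from 2.28 to 40.6 FPKM, the VEGF receptor Flt1 from 0.462 to 12.7 FPKM and the endothelial lectin Clec14a from 0.241 to 10.6 FPKM. Of 20 pan-endothelial genes 18 rose and 1 fell (adjusted Fisher's exact p = 9.8e-09), with a median log2 fold of 2.65, while the macrophage median fell by 1.12. Fli1, an ETS factor also active in blood cells, fell from 58.3 to 39.1 FPKM, and Egfl7, at 47.7 and 64.7 FPKM, did not pass.

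Most genes of the blood-brain barrier and of permeable vessels rose, the latter with the higher median, a difference that was not tested. Slc38a5, an amino acid transporter, rose from 1.32 to 21.3 FPKM, Itm2a from 17.8 to 144 FPKM and the forkhead factor Foxf2 from 1.01 to 12.2 FPKM. Plvap, which forms the diaphragms of fenestrae and caveolae, rose from 3.44 to 36.4 FPKM, and Sdpr and Ptrf, the cavins of caveolae, from 0.642 to 14 and from 2.33 to 24.1 FPKM. Of 29 barrier junction and transporter genes 21 rose and 1 fell (adjusted Fisher's exact p = 3.6e-07), with a median log2 fold of 1.44. The gene that fell was Slco2b1, an organic anion transporter, from 119 to 53.0 FPKM. Of 10 permeable-vessel genes 8 rose and 0 fell (adjusted Fisher's exact p = 8.8e-04), with a median of 2.76. In the same groups the pan-endothelial median rose by 2.65 and the macrophage median fell by 1.12.

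Arterial, venous and sprouting genes also rose with the pan-endothelial genes, whose median log2 fold was 2.65. Igfbp3 and Apln, genes of sprouting tip cells, rose from 5.07 to 74.5 and from 0.475 to 14.3 FPKM, the arterial factor Sox17 from 0.340 to 6.16 FPKM, the Notch ligand Dll4 from 0.754 to 8.71 FPKM and the venous receptor Ephb4 from 2.65 to 21.7 FPKM. Of 18 tip cell genes 15 rose and 1, Ednrb, fell (adjusted Fisher's exact p = 1.1e-06), with a median of 1.79. Of 18 arterial genes 16 rose and 1, Nrp1, fell (adjusted Fisher's exact p = 8.7e-08), with a median of 1.73. Of 11 venous genes 9 rose and 1, Ctsc, fell (adjusted Fisher's exact p = 3.3e-04), with a median of 1.30. Of 10 flow-response genes 8 rose and 1, Klf2, fell (adjusted Fisher's exact p = 8.8e-04), with a median of 1.79. Nos3, the endothelial nitric oxide synthase, rose from 0.673 to 9.13 FPKM, and Klf2, a factor that shear stress induces, fell from 105 to 54.6 FPKM. The median of the macrophage markers fell by 1.12.

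Genes that TGF-β signalling induces were mostly higher in the group labelled as lacking its receptor. Ctgf, a matricellular protein, rose from 0.680 to 10.2 FPKM, Col1a2 from 25.9 to 208 FPKM and Tsc22d1 from 23.9 to 129 FPKM. Of 24 SMAD2/SMAD3 response genes 17 rose (adjusted Fisher's exact p = 8.1e-06), with a median log2 fold of 1.26. The 1 that fell, the ligand Tgfb1, went from 217 to 120 FPKM. With cell type markers left out after seeing the data, 14 of 20 rose (adjusted Fisher's exact p = 8.9e-05) and the median was 0.97. Of 17 SMAD1/SMAD5 response genes 16 rose and 1, Lfng, fell (adjusted Fisher's exact p = 1.7e-08), with a median of 1.32. Id1 and Id3, direct targets of bone morphogenetic proteins, rose from 4.66 to 30.2 and from 19.6 to 79.3 FPKM, and Gata2, a factor of endothelium and blood progenitors, from 1.61 to 29.2 FPKM. Beside these medians stand a rise of 2.65 for the pan-endothelial genes, of 2.41 for the fibroblast markers and of 1.89 for the pericyte markers, and a fall of the macrophage markers.

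Among 31 components of the TGF-β and BMP pathways 17 rose and 3 fell, or 18 and 3 adjusted over the list alone (adjusted Fisher's exact p = 6.9e-04), with a median log2 fold of 0.58. Lrrc32, which holds latent TGF-β on the cell surface, rose from 0.491 to 11.9 FPKM, the co-receptor Tgfbr3 from 0.780 to 6.01 FPKM, the ligand Tgfb3 from 0.963 to 6.52 FPKM and the latency protein Ltbp4 from 2.56 to 15.6 FPKM. Lrrc33, which holds latent TGF-β on microglia, fell from 253 to 127 FPKM, as did Bmp2 from 13.4 to 6.95 FPKM and Tgfb1. Tgfbr1, at 22.4 and 25.6 FPKM, and Smad4, at 32.1 and 37.1 FPKM, did not pass. The macrophage median fell by 1.12 and the pan-endothelial median rose by 2.65.

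Components and targets of Wnt, Notch and VEGF signalling rose. Tcf7, a nuclear effector of β-catenin, rose from 0.806 to 18.2 FPKM, its target Apcdd1 from 6.77 to 37.3 FPKM and the receptor Fzd6 from 0.642 to 7.26 FPKM. Of 24 Wnt genes 18 rose and 1, Lrp5, fell (adjusted Fisher's exact p = 1.1e-06), with a median log2 fold of 1.49. The Notch target genes Hes1 and Nrarp rose from 2.59 to 21.5 and from 2.31 to 17.3 FPKM. Of 15 Notch genes 11 rose and 2, Rbpj and Lfng, fell (adjusted Fisher's exact p = 3.0e-04), with a median of 1.64. Vegfa, the ligand of Kdr, rose from 2.08 to 26 FPKM. Of 17 genes of the VEGF and angiopoietin axis 14 rose and 2, Nrp1 and Vegfb, fell (adjusted Fisher's exact p = 3.6e-06), with a median of 1.80 that became 2.72 at a minimum of 5 FPKM. The pan-endothelial median was 2.65, and 4 genes of this last list are also pan-endothelial.

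Genes of the basement membrane, of matrix proteases and of mesenchymal transition rose for the most part. Col4a1 and Col4a2, the type IV collagen chains of vascular basement membrane, rose from 11 to 164 and from 7.14 to 85.8 FPKM, the laminin gene Lama4 from 1.64 to 21.7 FPKM and Nid1 from 2.74 to 30.3 FPKM. Of 18 basement membrane genes 17 rose and 0 fell (adjusted Fisher's exact p = 6.3e-09), with a median log2 fold of 2.28. Of 15 matrix proteases and inhibitors 11 rose and 0 fell, or 11 and 1 adjusted over the list alone (adjusted Fisher's exact p = 3.0e-04), with a median of 1.76. They included the inhibitor Timp3, from 1.87 to 20.5 FPKM, and the membrane protease Mmp14, from 9.77 to 50.8 FPKM. Of 14 endothelial-to-mesenchymal transition genes 10 rose and 1, Zeb2, fell, or 10 and 2 adjusted over the list alone (adjusted Fisher's exact p = 7.4e-04), with a median of 1.29. Cdh2, or N-cadherin, rose from 6.26 to 25.2 FPKM, and Twist1 from 3.08 to 13.1 FPKM. Of 14 integrins 7 rose and 1, Itgb5, fell, or 8 and 2 adjusted over the list alone (adjusted Fisher's exact p = 0.101, and 0.0316 when genes were called at q under 0.01), with a median of 0.72. At a minimum of 5 FPKM, 2 of 8 integrins rose (adjusted Fisher's exact p = 0.768) and their median was 0.0103. Itgb3, a subunit on platelets and endothelium, rose from 0.439 to 20.1 FPKM. Over the same groups the fibroblast median rose by 2.41.

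Genes linked to vascular malformation and brain haemorrhage, and genes of hypoxia, rose in part. Of 18 malformation and haemorrhage genes 11 rose and 1, Ccm2, fell, or 12 and 2 adjusted over the list alone (adjusted Fisher's exact p = 0.0023), with a median log2 fold of 1.52. Without the members that are also cell type markers, a choice made after seeing the data, 8 of 15 rose (adjusted Fisher's exact p = 0.0289) and the median was 0.57. Foxc1, which when lost causes cerebral small vessel disease, rose from 1.87 to 12.2 FPKM. Of 31 hypoxia and glycolysis genes 16 rose and 1, Pfkfb4, fell (adjusted Fisher's exact p = 0.0027), with a median of 0.66. The oxygen sensor gene Egln3 rose from 0.523 to 10.2 FPKM and Bhlhe40 from 0.488 to 11.7 FPKM, while the glycolytic genes Ldha, at 758 and 853 FPKM, and Pgk1, at 185 and 200 FPKM, did not pass. The macrophage markers fell by 1.12 and the erythroid markers rose by 2.39 in the median.

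Some cell cycle genes fell in the Tgfbr2-deficient group, but the medians of both lists lay within the central 95% of random lists matched on expression, at percentiles of 3.17 for S-phase and 19.3 for G2/M genes. Cdt1, which licenses replication origins, fell from 40.3 to 23.8 FPKM, the helicase subunit Mcm5 from 95.2 to 58.8 FPKM and the mitotic cyclin Ccnb2 from 86.4 to 44.0 FPKM. Of 21 S-phase genes 9 fell and 0 rose, or 13 and 0 adjusted over the list alone (adjusted Fisher's exact p = 0.0046, and 0.376 when genes were called at q under 0.01), with a median log2 fold of −0.50, which centring on ribosomal protein genes makes 0.0382 by construction. Of 21 G2/M genes 6 fell and 0 rose, or 5 and 0 adjusted over the list alone (adjusted Fisher's exact p = 0.186), with a median of −0.38, which that centring makes 0.16. The macrophage median fell by 1.12 in the same groups.

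Immediate-early, inflammatory and interferon genes moved in both directions. Besides Fos, Egr1 fell from 94.8 to 34.0 FPKM, Zfp36, which destabilises cytokine transcripts, from 401 to 154 FPKM and the chemokine Ccl2 from 107 to 47.6 FPKM. Vcam1, a leukocyte adhesion molecule, rose from 3.22 to 16.4 FPKM and Rsad2, an antiviral protein, from 4.86 to 9.61 FPKM. Of 17 immediate-early and dissociation genes 6 fell and 3 rose (adjusted Fisher's exact p for lower genes = 0.0607, 0.0035 when genes were called at q under 0.01 and 0.323 at a minimum of 5 FPKM), with a median of −0.26 that became 0.28 under ribosomal centring. Of 13 inflammatory genes 3 fell and 1 rose (adjusted Fisher's exact p = 0.554 and 0.451), with a median of −0.09 that became 0.45. Of 20 interferon genes 5 fell and 1 rose, or 2 and 1 adjusted over the list alone (adjusted Fisher's exact p = 0.298 and 0.117), with a median of −0.25 that became 0.29. The macrophage median fell by 1.12.

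Ribosomal protein genes and reference genes give the background of abundant transcripts. Of 22 ribosomal protein genes 12 fell and 0 rose (adjusted Fisher's exact p = 7.4e-05, and 0.172 when genes were called at q under 0.01), with a median log2 fold of −0.54, at percentile 32.8 of the random lists, that is 0 by construction when folds are centred on them. Rpl10 fell from 461 to 282 FPKM. Of 14 reference genes 3 fell and 0 rose (adjusted Fisher's exact p for lower genes = 0.575), with a median of −0.23 that became 0.32 under ribosomal centring. They included Gusb, a lysosomal glucuronidase, from 283 to 132 FPKM, and Hprt from 201 to 105 FPKM.

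**Figure D3:**
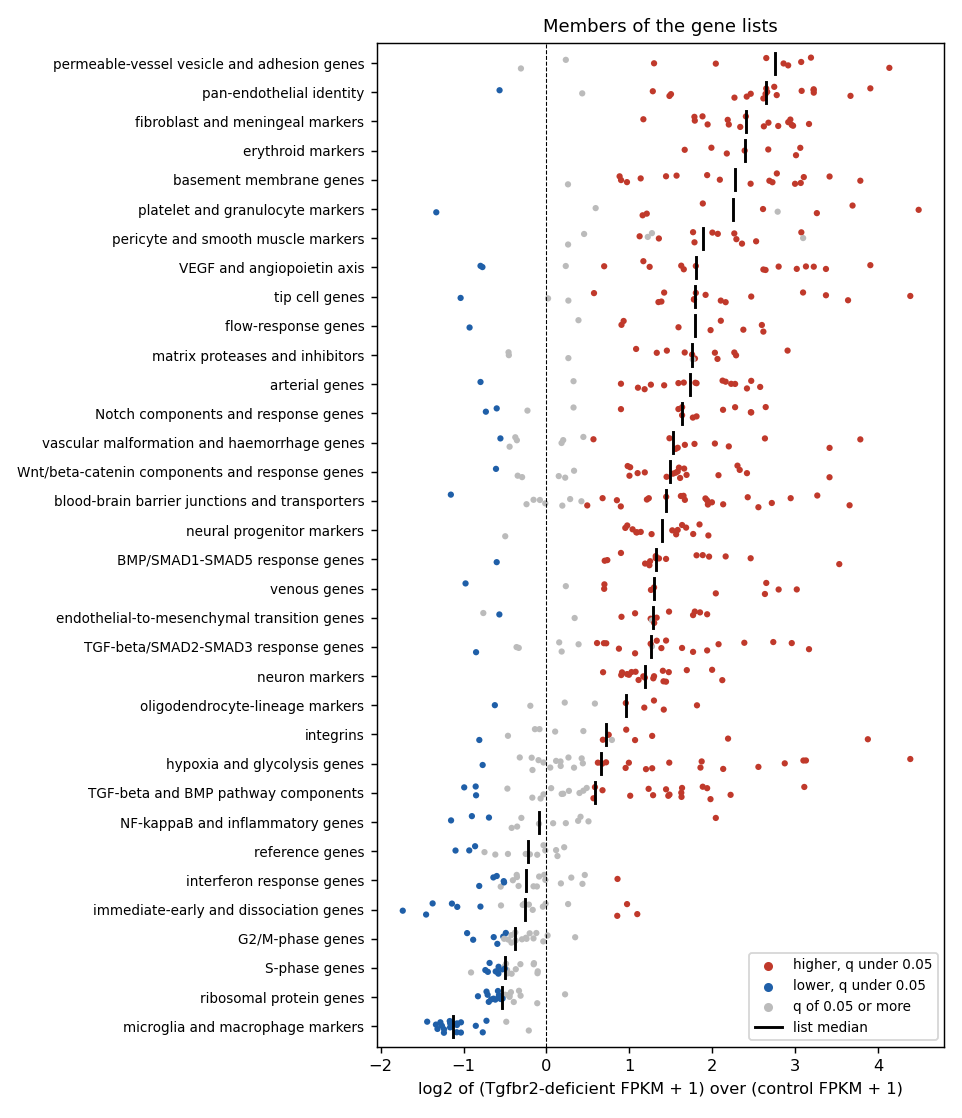
Log2 fold of each tested member of 34 gene lists, on FPKM + 1, Tgfbr2-deficient over control group (horizontal axis), with lists in order of their median (black bar). Red points are higher and blue points lower at q under 0.05 in the authors' deposited table, and grey points did not pass. List medians run from −1.12 for microglia and macrophage markers to 2.76 for permeable-vessel genes, and the S-phase, G2/M, inflammatory, interferon, immediate-early and reference medians turn positive by construction when 0.54 is added by centring on ribosomal protein genes.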

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

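The values in this part were picked after they were seen, and no test was made on them. Outside the genes tested by the authors, 34 entries were listed at 0 in the control group and at 10 FPKM or more in the Tgfbr2-deficient group, and all 34 carry symbols of microRNAs or small nucleolar RNAs. The largest 3, picked out because they lie outside the tests and above the control value, were Snord19 at 61.7 FPKM, Snord57 at 40.5 FPKM and Mir1956 at 40.3 FPKM. In the other direction, 27 entries were listed at 0 in the Tgfbr2-deficient group and at 10 FPKM or more in the control group, 26 of them with such symbols, the largest Mir1196 at 56.8 FPKM. No test of these entries is given. Without read counts a value of 0 does not show absence, and it is unknown how few reads the high values rest on.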

How the results depend on the processing

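No paired analysis was possible because the table gives 1 value per group, although library titles share numbers, and for the same reason the replicate block, leaving out each library, a per-library pseudocount, another tool and other splits of the libraries were not run. The 3195 higher and 1966 lower genes became 1643 and 1865 at 5 FPKM (46.8% higher against 61.9%, since fewer genes of low abundance were tested), 2712 and 1026 at q under 0.01, and 2688 and 368 with a log2 fold of at least 1. The other 6 settings gave 3096 to 3486 higher and 1837 to 1970 lower genes. Among these, both centrings kept the deposited q-values and could only drop lower genes, so their count of higher genes was fixed by construction. The number of lists with more higher genes stayed at 24 or 25 and of those with more lower genes at 2 or 3. Among list calls, taken for more or for fewer genes than in the other tested genes, 7 no longer passed and 3 newly passed. Those lost include the S-phase, G2/M, macrophage and ribosomal lists at 5 FPKM, where the result lost was a lack of higher genes. Centring on ribosomal protein genes, chosen after seeing the data, adds 0.54 to every log2 fold by construction and turned Tgfbr2 to 0.0700 (q = 0.0953 in the authors' deposited table) and the medians of S-phase genes to 0.0382, G2/M genes to 0.16, inflammatory genes to 0.45, interferon genes to 0.29, immediate-early genes to 0.28 and reference genes to 0.32. Of the other genes that the naming rule picks, Tap1 turned, to 0.0301 under that centring, and 551 comparisons of gene and setting gave no turn and no change of call. The settings compared were a pseudocount of 0.1 FPKM, both centrings and recomputed q-values. Only the recomputed q-values could change a call and only the centrings could turn a sign, so most of this agreement was fixed in advance. Calls of single genes at q under 0.01 or at 5 FPKM were not compared. Genes named outside that rule were not included. Of the 20 genes ranked by fold, 13 were shared with the ranking at a pseudocount of 0.1 FPKM. Depth is unknown, so no limit of detection was set.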

Other observations

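The tests in this part were chosen after the result was seen, except that over barrier genes of low control level on FPKM + 1. Further genes of mast cells and megakaryocytes rose, in lists drawn up because such genes led the ranking by fold, so no test of these lists is given. Kit, the stem cell factor receptor that mast cells and progenitors carry, rose from 1.98 to 27.8 FPKM and Slc45a3 from 0.602 to 13.3 FPKM. Gp5 and Treml1, platelet surface proteins, rose from 0.282 to 16.6 and from 0.315 to 13.5 FPKM. Of the tested genes not already named, 2 of 5 mast cell genes and 5 of 7 megakaryocyte genes passed as higher. The others did not pass, though all had higher values in the Tgfbr2-deficient group. Among them Tpsab1 stood at 0.0664 and 12.5 FPKM (q = 0.297) and Clec1b at 0.107 and 10.6 FPKM (q = 0.181 in the authors' deposited table). Without values per library it could not be told how many libraries carried any of these rises.

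Genes of haem and iron handling and of the sex chromosomes were also looked at. Hmox1, which breaks down haem, rose from 570 to 1065 FPKM and Blvrb from 260 to 393 FPKM. Of 5 haem and iron handling genes 2 rose (adjusted Fisher's exact p = 0.618), with a median log2 fold of 0.59 at percentile 99.6 of random lists matched on expression. Xist, expressed from the inactive X chromosome of females, went from 3.21 to 5.74 FPKM with q = 0.0024 in the authors' deposited table. Of 4 Y-linked genes, 0 passed in either direction, though all 4 had lower values in the Tgfbr2-deficient group, with a median log2 fold of −0.53 at percentile 0.11 of the random lists. Ddx3y stood at 4.52 and 2.60 FPKM. The sex of the embryos is not given in the labels.

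Macrophage markers fell while markers of endothelial, mural, fibroblast, neuronal and blood cells rose. A single scaling factor, as from globin transcripts taking part of the libraries, would move all lists alike. The pan-endothelial median exceeded the neuron median by 1.46 on the log2(FPKM + 1) scale (two-sided permutation over genes, p = 0.00011). On the deposited folds of the authors' deposited table the difference was 1.38 (permutation p = 0.0028). Such a factor as the only cause is therefore argued against. A factor acting beside other changes would cancel in this difference, so the test cannot exclude one. A lower share of macrophages alone would raise alike only those genes that other cells express and macrophages do not. How far macrophages express the list members was not measured here, so this difference cannot decide on a lower share of macrophages alone. A floor of genomic DNA under all genes is argued against by 1117 olfactory receptor entries, whose mean rise was 0.00761 FPKM (standard error over entries 0.00203) beside 1.30 FPKM for the smallest median rise of these lists. A change in the mix of sorted cells, in macrophages alone or in several types by different amounts, may account for the pattern. The loss of Tgfbr2 itself remains an untested biological explanation.

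The libraries are labelled endothelial, yet in the control group the median of the microglia and macrophage list was 256 times that of the pan-endothelial list. This is consistent with macrophages among the sorted cells, of whose listed markers the most abundant in the control group were C1qb at 2432 FPKM and C1qc at 2026 FPKM, and the list shares no member with any other list. Sorting on TdTomato would remove macrophages without recombination of the reporter, and the Cre driver, which would say whether they recombine it, is not given in the sources used here. That the table holds other samples than the labels say cannot be told apart from this, since Tgfbr2 differed with q = 0.0953 in the authors' deposited table and no values per library were analysed. No biological explanation was tested.

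All 6 entries with the status for too many fragments, at 4 distinct positions, were globin entries listed at 0 in the Tgfbr2-deficient group. The 7 erythroid markers with an estimate rose by a median log2 of 2.39, which argues against fewer erythroid transcripts as the reason for these zeros. A failed estimate at loci that held too many reads may account for them, as the status itself says, so the zeros carry no level.

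As hypotheses, the tip cell and barrier lists were compared with the pan-endothelial list. The tip cell median differed by −0.86 (permutation p = 0.0523 adjusted over 2 comparisons) and, with 0.1 FPKM added in place of 1 FPKM, by −0.32 (adjusted permutation p = 0.476), so no difference was shown. The barrier median differed by −1.20 (adjusted permutation p = 0.0156) but with 0.1 FPKM added by −0.82 (adjusted permutation p = 0.179), so whether barrier genes rose less than genes of endothelial identity depended on the scale. Barrier members with a high level in the control group could have lowered that median, but over the 17 barrier and 16 pan-endothelial members under 10 FPKM in the control group the difference was −0.79 (permutation p = 0.0105), and −0.78 with 0.1 FPKM added (permutation p = 0.0234). Several barrier genes are also expressed in other brain cells, so a mixture of cell types remains open.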
